A study of Mus musculus with 12 samples.

How the data were processed

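Gene expression was measured on 12 arrays, 3 for each of 4 groups: c-kit+ and CD44+ cells from bone marrow cultures of female C57BL/6 mice, given 1 nM 17β-estradiol or none. Per the labels, total RNA was amplified, labelled with biotin and hybridized to Affymetrix mouse arrays. The deposited values are on the log2 scale and were made by the authors with RMA, which corrects background, quantile-normalizes the probes and summarises each probe set by median polish; this comes from the submitters' processing notes, and the version is not given in the sources used here. The values of all arrays together ran from 2.47 to 14.81, array medians lay between 4.75 and 4.84, and no value was missing. The number of arrays limits the precision.

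Probe sets were named from the platform's annotation table. Of 45101 probe sets, 64 were controls, 34945 named 1 gene, 932 named several and 9160 were unnamed here. Each gene was represented by its probe set with the highest mean over all 12 arrays, which gave 18193 genes (9183 with 1 probe set and 9010 with more). Probe sets with no gene or several were left out of the comparisons and are given in the closing section. Values entered as deposited, with no filter and no renormalization.

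Genes were tested with limma 3.58.1 in R 4.3.3: a model with 1 mean per group over all 12 arrays, moderated by empirical Bayes without a trend, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The 4 comparisons were estradiol minus control in c-kit+ cells, the same in CD44+ cells, the difference of these effects, and c-kit+ minus CD44+ cells in control cultures. Standard errors are those of the moderated fit, and fold changes are powers of 2 of the log2 differences. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

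The comparisons, the tests, 24 gene lists for pathways and cell types, the rule for named genes and the alternatives other than those said to be added later were fixed before the data were examined. Of 516 list entries 471 were measured, 5 of them through an older symbol, and these are 459 genes, 11 of which stand in more than 1 list. Lists were tested with limma's camera (preset inter-gene correlation of 0.01, two-sided), adjusted over the 24 lists; camera with an estimated correlation and fry, whose directional p asks whether a list's genes move on balance in 1 direction, were run beside it. Members were also adjusted over the list alone. Genes are named in the text by this rule: in each comparison, the 12 largest rises and the 12 largest falls among genes that passed and whose groups of 3 arrays do not overlap (no such demand for the difference of effects); where fewer than 12 passed in a direction, it was filled to 6 with the smallest p-values, given as values that did not pass; up to 4 members of smallest p from each list; and Kit, Cd44, Esr1, Esr2, Gper1 and Pgr. Genes outside this rule are said to be named after their values were seen.

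Whether replicate numbers pair the arrays was checked by correlating each array's deviations from its group mean between groups. Equal numbers were to correlate above 0.1 and match best in all 3 cases. CD44+ control and estradiol arrays met this (0.303, 0.368 and 0.322), so a fit with the replicate number as a block stands beside that comparison; c-kit+ arrays (0.345, 0.092 and 0.253) and control arrays of the cell types (0.175, 0.122 and -0.208) did not. Across the cell types it was met by the estradiol arrays (0.447, 0.192 and 0.312) and by c-kit+ estradiol with CD44+ control arrays (0.31, 0.142 and 0.213). RNA quality was read from the 3' and 5' control probe sets of Gapdh and Actb and compared with exact permutation tests, two-sided, 8 in the family.

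Simulated data were made with noise independent between genes and arrays, so without replicate effects or outlying arrays. The pipeline was tested on these data with 50 changed genes, drawn at random, at each size. For c-kit+ cells it recovered 26% of changes of 0.5 on the log2 scale, 96% of those of 1 and 100% of those of 1.5 and 2, with 7 false among 168 calls. For CD44+ cells it recovered 34%, 96%, 98% and 100% at these sizes (5 false of 169), for the difference of effects 2%, 60%, 96% and 100% (6 false of 135), and for the cell types 24%, 84%, 98% and 100% (7 false of 160). The alternatives were the mean of a gene's probe sets, genes at or above the median level, every probe set, quantile normalization over all arrays or within a cell type, median centring, a trend with robust moderation, array weights, the replicate block, the 6 arrays of the comparison alone, other thresholds, estradiol in place of control cultures, and leaving out each array in turn. Added after the data were seen were the Gapdh measure as a covariate, the block together with estradiol in place of control cultures and, for CD44+ cells, leaving out c-kit+ control replicate 3. Other splits of the samples were drawn as described with their results.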

Results

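Bone marrow cultures from female C57BL/6 mice aged 6 weeks were given 1 nM 17β-estradiol, the main circulating estrogen, for 1 week or left without it. From them c-kit+ cells, which the labels call stem cells, and CD44+ cells, which they call stromal cells, were collected. Each of the 4 groups (c-kit+ control, c-kit+ estradiol, CD44+ control and CD44+ estradiol) had 3 Affymetrix expression arrays, 12 in all. The arrays gave log2 values for 45101 probe sets, of which 34945 named 1 gene each, and 18193 genes were tested. The number of arrays limits the precision of every value here. The labels do not say whether replicates were separate cultures or animals, so the p-values measure the spread between these samples alone.

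Inflammatory genes were higher in c-kit+ cells from estradiol cultures than in those from control cultures. Il6, a cytokine of inflammation and bone turnover, rose by 2.66 on the log2 scale (SE 0.27, 6.34-fold, 3 arrays against 3, adjusted p = 0.000887), from a mean of 4.04 in control arrays to 6.7. That control mean lies near background, since 9 Y-linked probe sets, in female mice, read up to 3.98, and this limits how well the fold is known. Il12b, the subunit that interleukins 12 and 23 share, rose by 2.32 (SE 0.22, 4.98-fold, adjusted p = 0.000887). Cxcl10, a chemokine induced by interferon, rose by 1.56 (SE 0.15, 2.95-fold, adjusted p = 0.000887). Ptgs2, which encodes the prostaglandin synthase COX-2, rose by 1.4 (SE 0.16, adjusted p = 0.00269). Cd40, a receptor of antigen-presenting cells, rose by 1.29 (SE 0.16, adjusted p = 0.0049). For each of these 5 genes all 3 estradiol arrays lay above all 3 control arrays, which the rule for naming the largest rises demands.

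In this comparison of estradiol with control cultures in the c-kit+ fraction 33 genes passed, 32 higher and 1 lower, and 814 had an unadjusted p under 0.05. Further rises belonged to Kdm6b, a histone H3 lysine 27 demethylase (log2 1.32, adjusted p = 0.00697), Nfkbie, an inhibitor of NF-κB (1.17, adjusted p = 0.000887), and Rasgef1b (1.21, adjusted p = 0.0484). Others that rose were Cd69, an early activation marker of leukocytes (1.17, adjusted p = 0.00697), and Mefv, which encodes pyrin (1.16, adjusted p = 0.00735). The gene that fell was the pseudogene Hmga2-ps1 (log2 -1.17, SE 0.16, adjusted p = 0.00697). The next lowest p-values among lower genes, which did not pass, belonged to Txnip (-0.86, adjusted p = 0.0519), Zfp87 (-0.55, adjusted p = 0.114) and Frat2 (-0.85, adjusted p = 0.125). Without c-kit+ estradiol replicate 2 the count was 10, and Kdm6b, Rasgef1b, Cd69, Mefv, Il1b, Il1a, Hmga2-ps1 and Csf2 lost their calls. Without estradiol replicate 3 it was 21, and Rasgef1b, Il1b, Il1a and Csf2 lost theirs. Calls were also lost without control replicate 1 (Csf2, 33 genes), control replicate 2 (Rasgef1b, Il1b and Csf2, 25 genes), control replicate 3 (Rasgef1b and Csf2, 45 genes) and estradiol replicate 1 (Rasgef1b, 28 genes). The 6 c-kit+ arrays alone gave 2 genes, Cxcl10 and Nfkbie. Array weights gave 55 and a replicate block gave 62. The replicate numbers missed the pairing criterion in these arrays, with 1 of the 3 correlations at 0.092 where over 0.1 was asked.

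**Figure D1:**
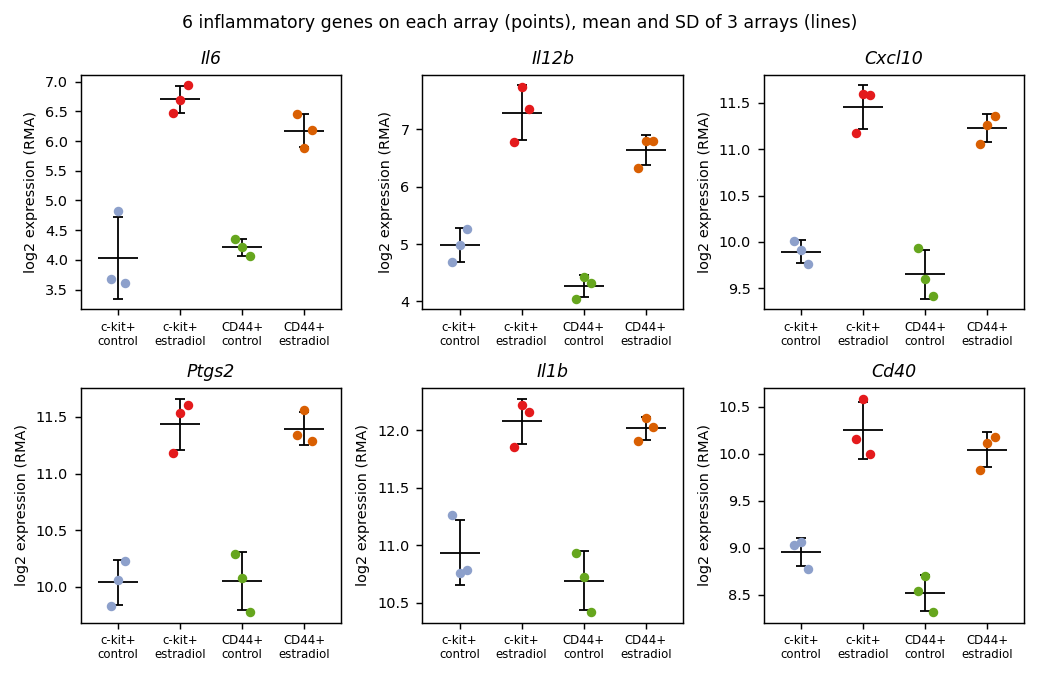
Log2 expression of 6 genes on each of the 12 arrays (points) in the 4 groups, with the mean and SD of 3 arrays (lines). In both cell types the 3 estradiol arrays lie above the 3 control arrays for each gene, which the rule for naming the largest rises demands. Il6 in c-kit+ cells goes from a mean of 4.04 to 6.7.

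Of 24 gene lists fixed before the data were examined, 7 shifted in c-kit+ cells by the camera test with a preset correlation. Of these 2, the inflammatory cytokine list and the dendritic cell and MHC class II list, also passed with an estimated correlation. Of the 20 measured inflammatory cytokine genes 5 rose (Il6, Il12b, Ptgs2, Il1b and Il1a), none fell and 15 did not pass. With p-values adjusted over the list alone, 11 rose. Il1b rose by 1.14 (SE 0.16, adjusted p = 0.00951) and Il1a, like Il1b a form of interleukin 1, by 1.09 (SE 0.16, adjusted p = 0.0124). The median of the list was 0.68 (adjusted p = 2.09e-24; adjusted p = 0.00483 with an estimated correlation). None of the 17 dendritic cell and MHC class II genes passed over all genes and 1 did when adjusted over the list alone. Its members included Cd83 (log2 0.86, adjusted p = 0.27) and Cd80 (0.41, adjusted p = 0.694), neither of which passed. The median was 0.23 (adjusted p = 6.29e-05; adjusted p = 0.0479 with an estimated correlation).

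Of the 25 interferon response genes 1 rose, Cxcl10, and 24 did not pass. There were 5 that rose when adjusted over the list alone, and the list median was 0.36 (adjusted p = 2.21e-12; adjusted p = 0.17 with an estimated correlation). None of the 20 immediate early and dissociation stress genes passed, and 6 did when adjusted over the list alone. Their median was 0.42 (adjusted p = 3.46e-11; adjusted p = 0.17 with an estimated correlation), and Nr4a1, an orphan nuclear receptor, had a value of 0.9 (adjusted p = 0.299). In the niche and bone factor list 1 of 25 genes rose, Csf2, which encodes the growth factor GM-CSF (log2 0.86, adjusted p = 0.0496). In it 7 rose when adjusted over the list alone, and the median was 0.12 (adjusted p = 8.19e-05; adjusted p = 0.17 with an estimated correlation). Lif, a cytokine of the interleukin 6 family, had 0.72 (adjusted p = 0.0643) and Jag1, a Notch ligand, 0.89 (adjusted p = 0.0759) in that list, neither of which passed. Over the arrays left out and the other settings the medians ran from 0.23 to 0.57 for the interferon list and from 0.07 to 0.48 for the niche and bone factor list. For the dendritic cell list the range was 0.17 to 0.37.

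None of the 23 matrix remodelling genes passed in c-kit+ cells, and 1 did when adjusted over the list alone. The median was 0.27 (adjusted p = 0.0115; adjusted p = 0.761 with an estimated correlation), and from 0.12 to 0.39 over the alternatives. None of the 29 cell cycle genes passed either way. This list shifted down with a median of -0.065 (adjusted p = 0.0438; adjusted p = 0.761 with an estimated correlation). Without 1 array the adjusted p of the matrix list was 0.21 (control replicate 1), 0.407 (control replicate 2), 0.209 (estradiol replicate 1) or 0.107 (estradiol replicate 3). That of the cell cycle list was 0.66 (control replicate 1), 0.06 (control replicate 3), 0.221 (estradiol replicate 2) or 0.369 (estradiol replicate 3). Its median turned to 0.014 without control replicate 1 and to 0.0042 without estradiol replicate 2. Its adjusted p was also above the threshold with gene means, the brighter genes alone, median centring, the block or the RNA-quality covariate, from 0.0543 to 0.128.

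The other 17 lists did not pass in c-kit+ cells (adjusted p from 0.0701 to 0.977, medians from -0.04 to 0.16), and none of their members rose or fell. Among them were the lists for stem and progenitor, mast, erythroid, megakaryocyte, neutrophil, macrophage, lymphoid, mesenchymal, adipocyte and endothelial cells. The osteoclast list had the lowest of these adjusted p-values, 0.0701, with Acp5, which encodes an osteoclast acid phosphatase, at 0.86 (adjusted p = 0.0903). None of the 27 estrogen response genes passed, and their median was 0.05 (adjusted p = 0.745). Pgr, which encodes the progesterone receptor, had a value of 0.08 and Esr1, the estrogen receptor α gene, 0.03 (both with adjusted p = 0.999). Esr2, Gper1, Kit and Cd44 lay between -0.03 and 0.21 and did not pass. Among these lists the median, the mean and the direction of the test differed in sign for the erythroid, endothelial, and hypoxia and glycolysis lists.

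In CD44+ cells, too, inflammatory genes were higher in estradiol than in control cultures. Il12b rose by 2.37 on the log2 scale (SE 0.22, 5.17-fold, 3 arrays against 3, adjusted p = 0.000669). Il6 rose by 1.97 (SE 0.27, 3.91-fold, adjusted p = 0.00513), from a control mean of 4.21, near background as well, to 6.17. Malt1, a protease that activates NF-κB downstream of antigen receptors, rose by 1.58 (SE 0.21, 2.99-fold, adjusted p = 0.00433). Cxcl10 rose by 1.57 (SE 0.15, 2.98-fold, adjusted p = 0.000669), and Cd40 by 1.52 (SE 0.16, 2.87-fold, adjusted p = 0.00129). Each of these 5 genes was higher on all 3 estradiol arrays than on all 3 control arrays, again as the rule for naming them demands.

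In CD44+ cells 53 genes passed, 51 higher and 2 lower, and 978 had an unadjusted p under 0.05. With the replicate number as a block, for which these arrays met the pairing criterion, 101 genes passed, 92 higher and 9 lower, and these included all 53. Kdm6b (log2 1.43, adjusted p = 0.00308), Mefv (1.38, adjusted p = 0.00217) and Ptgs2 (1.35, adjusted p = 0.00219) rose. So did 2610024D14Rik (1.88, adjusted p = 0.0175), Maff, a small Maf transcription factor (1.42, adjusted p = 0.0155), and Rab20, a small GTPase (1.39, adjusted p = 0.0186). The zinc finger gene Zscan22 fell by 0.82 (SE 0.12, adjusted p = 0.0119) and Ttc30a1, which encodes a protein of intraflagellar transport, by 0.59 (SE 0.11, adjusted p = 0.0494). Hmga2-ps1, with a value of -0.78, did not pass (adjusted p = 0.0765), nor did Zfp623 (-0.75, adjusted p = 0.0633). The count was 29 without CD44+ control replicate 2, 30 without control replicate 3, 29 without estradiol replicate 2 and 22 without estradiol replicate 3. In all 4 of these fits 2610024D14Rik, Maff, Rab20 and Ttc30a1 lost their calls, and Zscan22 did in those other than that without control replicate 3. Ttc30a1 also lost its call without control replicate 1 (76 genes) and estradiol replicate 1 (49 genes). Without c-kit+ control replicate 3, an alternative added after the data were seen, 97 genes passed. Array weights gave 1405 genes, 903 higher and 502 lower. The 6 CD44+ arrays alone gave 58, and Ttc30a1 and Lif lost their calls. With the mean of a gene's probe sets Il12b had 1.36 and 2610024D14Rik 0.94, and Lif (0.38) lost its call.

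Of the 24 lists 10 shifted up in CD44+ cells, of which 1, the inflammatory cytokine list, also passed with an estimated correlation. Its 5 members that rose were Il12b, Il6, Ptgs2, Il1b (log2 1.33, SE 0.16, adjusted p = 0.00307) and Il1a (1.03, adjusted p = 0.0151; named here after its value was seen). The other 15 did not pass, 14 rose when adjusted over the list alone, and the median was 0.71 (adjusted p = 7.91e-23; adjusted p = 0.00608 with an estimated correlation). Of the 25 interferon response genes 2 rose, Cxcl10 and the transcription factor gene Irf1 (0.96, adjusted p = 0.0295), and 5 did when adjusted over the list alone. The median was 0.39 (adjusted p = 2.19e-10; adjusted p = 0.245 with an estimated correlation). In the niche and bone factor list 1 of 25 genes rose, Lif (0.85, adjusted p = 0.0155), and 5 did when adjusted over the list alone. The median was 0.21 (adjusted p = 0.000514; adjusted p = 0.245 with an estimated correlation, and 0.083 among the brighter genes). Irf1 lost its call without CD44+ control replicates 2 or 3 or any of the 3 estradiol replicates (29, 30, 49, 29 and 22 genes), and Lif without control replicates 2 or 3 or estradiol replicates 1 or 3.

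None of the members of 7 further lists that shifted up in CD44+ cells passed over all genes. The median was 0.39 for the 20 immediate early and dissociation stress genes (adjusted p = 2.72e-07; adjusted p = 0.285 with an estimated correlation; 3 rose when adjusted over the list alone). It was 0.42 for the 23 matrix remodelling genes (adjusted p = 2.82e-05; adjusted p = 0.369 with an estimated correlation; none rose when adjusted over the list alone). It was 0.23 for the 17 cholesterol synthesis genes (adjusted p = 7.88e-05; adjusted p = 0.245 with an estimated correlation; none rose when adjusted over the list alone). Insig1, a sterol-regulated gene, had a value of 0.9 (adjusted p = 0.343). The 24 mesenchymal and osteoblast genes had a median of 0.38 (adjusted p = 0.004; adjusted p = 0.537 with an estimated correlation; 1 rose when adjusted over the list alone). Dmp1, a matrix protein gene of osteocytes, had 1.12 (adjusted p = 0.0541 over all genes). The 19 p53 target genes had a median of 0.24 (adjusted p = 0.00433; adjusted p = 0.335 with an estimated correlation; 4 rose when adjusted over the list alone), and Gadd45a had 0.98 (adjusted p = 0.253). The 22 macrophage and monocyte genes had a median of 0.13 (adjusted p = 0.034; adjusted p = 0.402 with an estimated correlation). The 14 osteoclast genes had a median of 0.16 (adjusted p = 0.034; adjusted p = 0.245 with an estimated correlation). In each of these lists 1 gene rose when adjusted over the list alone, and Cd14 had 0.48 (adjusted p = 0.125) and Acp5 0.88 (adjusted p = 0.0623).

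Several of these list calls in CD44+ cells rested on single arrays or settings. The adjusted p of the matrix list was 0.124 without control replicate 2 and 0.102 without estradiol replicate 1. That of the mesenchymal list was 0.663 and 0.227 without the same arrays, and that of the p53 list 0.114 without estradiol replicate 1 and 0.083 among the brighter genes. The macrophage list had 0.11 without control replicate 1, 0.0662 without control replicate 3, 0.1 without estradiol replicate 2 and 0.141 without estradiol replicate 3. It also had 0.0835 without c-kit+ control replicate 3, 0.562 after quantile normalization, 0.289 with array weights and 0.0856 among the brighter genes. The osteoclast list had 0.11 without control replicate 1, 0.0972 without estradiol replicate 2, 0.0915 without estradiol replicate 3, 0.196 among the brighter genes and 0.127 with array weights. Medians, too, moved over the arrays left out and the other settings. They ran from 0.19 to 0.53 for the interferon list, from 0.08 to 0.36 for the cholesterol list and from 0.11 to 0.41 for the niche and bone factor list. The range was 0.25 to 0.49 for the immediate early list, 0.21 to 0.84 for the matrix list, 0.07 to 0.8 for the mesenchymal list and 0.06 to 0.33 for the p53 list. For the macrophage list it was 0.01 to 0.18, and for the osteoclast list 0.08 to 0.19.

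The other 14 lists did not pass in CD44+ cells (adjusted p from 0.119 to 0.938, medians from -0.07 to 0.11). Among their members 1 rose, Cd83, a surface marker of mature dendritic cells (log2 1.23, adjusted p = 0.0266), in the dendritic cell and MHC class II list (16 of 17 not passed, adjusted p = 0.223). Cd83 lost its call without control replicates 2 or 3 or any of the 3 estradiol replicates (29, 30, 49, 29 and 22 genes). None of the 27 estrogen response genes passed, and their median was -0.02 (adjusted p = 0.927). Pgr had a value of 0.12 (adjusted p = 0.95) and Esr1 -0.02, and Kit and Cd44 had -0.08 and 0.21, none of which passed. Pgr lay near background here as well. The median, the mean and the direction of the test differed in sign for the estrogen response, stem and progenitor, adipocyte, endothelial and cell cycle lists.

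Setting the effects of both cell types side by side asks whether the changes with estradiol differed between them. In both cell types 25 genes rose, among them Il6, Il12b, Cxcl10, Ptgs2, Il1b, Cd40, Kdm6b, Mefv and Nfkbie. Arrays of both fractions carry the same replicate numbers, so these are not shown to be independent estimates. No gene fell past the threshold in both. All 61 genes that passed in either cell type had the same sign in both, and the effects correlated across these genes with r = 0.877 (genes are not independent replicates, and these were chosen by their calls). Over all genes r was 0.38 and Spearman's rho 0.158. The 28 genes called in CD44+ cells alone all moved the same way in c-kit+ cells with an unadjusted p under 0.05, as did the 8 called in c-kit+ cells alone in CD44+ cells.

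No gene passed limma's test of the difference between the effects (0 of 18193), and 296 had an unadjusted p under 0.05. Il6 had the difference 0.70 (SE 0.38, unadjusted p = 0.0868, adjusted p = 1), with 2.66 in c-kit+ and 1.97 in CD44+ cells. The values with the smallest p-values, which did not pass, included Btla, an inhibitory receptor of lymphocytes (-0.5), Nipal1, a magnesium transporter gene (-1.08), and Gm9947 (0.53), all with adjusted p = 1. In simulated data this test recovered 60% of differences of 1 on the log2 scale and 96% of those of 1.5. Those data had independent noise and genes drawn at random. The SE of Il6 (0.38) lies above the median SE of all genes (0.187), so these shares do not carry over to such genes.

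No list passed the test of the difference (adjusted p from 0.0501 to 0.98), and no list did with an estimated correlation. The cholesterol synthesis list had the lowest, with a median of -0.27 that lies toward the CD44+ cells (adjusted p = 0.0501; adjusted p = 0.84 with an estimated correlation). Its member Idi1, an isoprenoid enzyme gene, had -0.46. Leaving out 1 array passed 1 list (c-kit+ control replicate 1, c-kit+ control replicate 2, CD44+ control replicate 2 or CD44+ estradiol replicate 3), 2 lists (c-kit+ or CD44+ estradiol replicate 2), 3 lists (CD44+ control replicate 3) or 4 lists (c-kit+ estradiol replicate 1 or CD44+ control replicate 1). The replicate block passed 1 list, array weights 2 and the RNA-quality covariate 1. The median, the mean and the direction of the test differed in sign for the stem and progenitor, B lymphoid, interferon, and niche and bone factor lists.

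**Figure D2:**
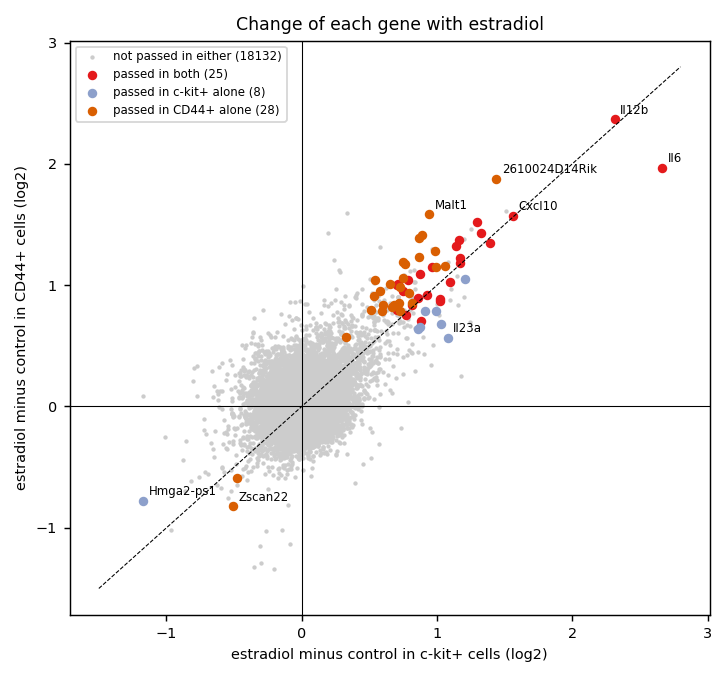
Log2 change with estradiol in c-kit+ cells (x axis) against that in CD44+ cells (y axis), 1 point per gene; colours mark the genes that passed in both (25), in c-kit+ alone (8) or in CD44+ alone (28), and the dashed line marks equal change. All 61 coloured genes have the same sign on both axes.

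Comparing the fractions in control cultures asks how the sorted populations differed without estradiol. Col1a2, a chain of type I collagen, was 10.3-fold higher in CD44+ than in c-kit+ cells (log2 difference -3.37, c-kit+ minus CD44+ here and below, SE 0.4, 3 arrays against 3, adjusted p = 0.000763). Ogn, a proteoglycan gene, had -3.46 (SE 0.47, adjusted p = 0.00151), F2r, the thrombin receptor gene, -3.39 (SE 0.33, adjusted p = 0.000272), and Efemp1, an extracellular matrix gene, -3.31 (SE 0.38, adjusted p = 0.00066). Higher in c-kit+ cells were Mertk, a macrophage receptor for apoptotic cells (1.02, SE 0.14, 2.03-fold, adjusted p = 0.0017), Cmklr1, the chemerin receptor gene (1.09, SE 0.15, 2.13-fold, adjusted p = 0.00146), and Npl, a sialic acid lyase gene (1.3, SE 0.19, adjusted p = 0.00259).

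Of the 18193 genes 418 differed, 98 higher in c-kit+ and 320 higher in CD44+ cells, and 2467 had an unadjusted p under 0.05. In the estradiol cultures 483 genes differed, of which 33 were higher in c-kit+ and 285 higher in CD44+ cells in both conditions. Further genes higher in CD44+ cells were Fscn1, which encodes an actin-bundling protein (-3.18, adjusted p = 0.000231), Cd24a (-3.11, adjusted p = 0.000103) and Ghr, the growth hormone receptor gene (-3.11, adjusted p = 0.000169). Further genes higher in c-kit+ cells were Hpse, the heparanase gene (1.45, adjusted p = 0.0271), and Fabp4, a fatty acid binding protein gene (1.17, adjusted p = 0.0219). Neither gene behind the sort passed. Kit had -0.04 (SE 0.12, adjusted p = 0.938), and its probe sets read from 3.79 to 4.22 and from 3.54 to 3.75 over all 12 arrays. These values lie near background (the 9 Y-linked probe sets had means from 2.91 to 3.63), where a difference says little about the mRNA. Cd44 had -0.19 (SE 0.14, adjusted p = 0.615), and its brightest probe set read from 11.76 to 12.46. The macrophage genes Lyz2, from 13.91 to 14.35, and Csf1r, from 13.86 to 14.11 at its brightest probe set, were measured on all 12 arrays and named here after their values were seen. Esr1 had 0.18 (adjusted p = 0.688), Esr2 had 0, Gper1 had -0.06 and Pgr had -0.01, none of which passed. The value of Esr1 is that of its brightest probe set. A dimmer one read 4.92 (SD 0.04) in c-kit+ and 4.3 (SD 0.27) in CD44+ control arrays, and another, near background, 3.53 and 3.62. Like Kit, the genes Esr2, Gper1 and Pgr lay near background.

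Signs of RNA quality moved with the cell type. The difference between the 3' and 5' control probe sets of Gapdh was 5.03 ± 0.7 (SD) on the log2 scale over the 6 c-kit+ arrays and 3.67 ± 0.56 over the 6 CD44+ arrays (exact permutation test, two-sided p = 0.00433, 0.0173 adjusted over 8 tests). That of Actb was 3.27 ± 0.95 and 1.86 ± 0.25 (exact permutation test, two-sided p = 0.00216, adjusted p = 0.0173). Between estradiol and control arrays these measures differed by -0.07 and -0.13 in c-kit+ cells and by 0.07 and 0 in CD44+ cells (exact permutation test, p from 0.9 to 1, where 3 arrays against 3 allow no p under 0.1). With the Gapdh measure as a covariate, added after the data were seen, 254 genes differed between the cell types, 199 of them among the 418. In that fit Hpse, Fabp4, C1qb, Mrc1, Csf1, Hoxa9, Lmo2, Ebf1, Klf2, Krt19, Eda2r and H2-Ab1 lost their calls. The measure differs between the fractions (5.07 against 3.64 in control arrays), so the covariate can take up part of their difference. After adjustment 0 genes followed the measure itself, so the lost calls do not show an effect of RNA quality. The count of genes that differed was 238 without c-kit+ control replicate 1 and 221 without CD44+ control replicate 3, and 191 genes passed without each of the 6 control arrays in turn. Hpse lost its call without c-kit+ control replicates 1 or 3 (238 and 456 genes) or CD44+ control replicates 2 or 3 (414 and 221 genes), and Fabp4 without c-kit+ control replicate 1 or CD44+ control replicates 2 or 3. The count was 1058 with array weights and 693 with a replicate block, for which the control arrays missed the pairing criterion. With the 6 control arrays alone it was 196, and 22 of the 53 named genes called here lost their calls. Among them were Npl, Hpse, Fabp4, Hoxa9, Lmo2, Csf3r, C1qb, Mrc1, H2-Eb1, H2-Aa, Ebf1, Scd1, Dcstamp, Csf1, Klf4, Klf2, Krt19 and Eda2r. With the mean of a gene's probe sets differences were smaller for Fscn1 (-0.93), Ghr (-1.65), Cmklr1 (0.43), Col5a1 (-1.68), Acta2 (-0.8), Hoxa9 (-1.16), Scd1 (-1.08) and Ebf1 (-0.79), which kept their calls. In that fit Ankrd24, Insyn2a, Fcgr1 and C1qb lost theirs.

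Of the 24 lists 6 differed between the fractions, and none of them passed with an estimated correlation. With fry 7 lists passed, 5 of them among these 6. The 5 were matrix remodelling (fry adjusted p = 0.00154), mesenchymal (0.00794), niche and bone factor (0.0236), macrophage (0.0236) and neutrophil granule (0.0317). The interferon list did not pass fry (adjusted p = 0.432). The stem and progenitor list (fry adjusted p = 0.027) and the dendritic cell list (0.0477) passed fry, both toward CD44+ cells. Of the 23 matrix remodelling genes 17 were higher in CD44+ cells and 6 did not pass. Adjusted over the list alone, 18 were higher, and the median was -2.08 (adjusted p = 3.2e-29; adjusted p = 0.0779 with an estimated correlation). They included the type V collagen genes Col5a1 (-3.04, adjusted p = 0.000231) and Col5a2 (-3.2, adjusted p = 0.000654), Thbs2 (-2.94, adjusted p = 0.000209) and Timp1, an inhibitor of metalloproteinases (-2.67, adjusted p = 0.000475). Of the 24 mesenchymal and osteoblast genes 12 were higher in CD44+ cells and 12 did not pass. The higher ones included the smooth muscle genes Acta2 (-2.3, adjusted p = 0.000231) and Tagln (-2.37, adjusted p = 0.000523). Of them 13 were higher when adjusted over the list alone, and the median was -1.5 (adjusted p = 8.04e-18; adjusted p = 0.148 with an estimated correlation). Of the 25 niche and bone factors 5 were higher in CD44+ cells and 20 did not pass. They included the chemokine gene Cxcl12 (-2.84, adjusted p = 0.00257), Tgfb3 (-1.75, adjusted p = 0.00324) and the macrophage growth factor gene Csf1 (-1.17, adjusted p = 0.00923), which lost its call without CD44+ control replicate 3 (221 genes). Adjusted over the list alone, 9 were higher in CD44+ and 2 in c-kit+ cells, and the median was -0.17 (adjusted p = 5.56e-05; adjusted p = 0.148 with an estimated correlation).

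Of the 22 macrophage and monocyte genes 3 were higher in c-kit+ cells and 19 did not pass. The 3 were the Fc receptor gene Fcgr1 (0.71, adjusted p = 0.0211), the complement gene C1qb (0.55, adjusted p = 0.0294) and the mannose receptor gene Mrc1 (0.66, adjusted p = 0.0353). Adjusted over the list alone, 5 were higher, and the median was 0.23 (adjusted p = 0.000329; adjusted p = 0.15 with an estimated correlation). The 18 neutrophil granule genes shifted toward CD44+ cells with a median of -0.2 (adjusted p = 0.00207; adjusted p = 0.148 with an estimated correlation; adjusted p = 0.0677 with the RNA-quality covariate). The 1 member that passed, the receptor gene Csf3r, was higher in c-kit+ cells (0.72, adjusted p = 0.0427). Adjusted over the list alone, 1 was higher in c-kit+ and 5 in CD44+ cells. None of the 25 interferon response genes passed, and 1 did when adjusted over the list alone. The median was 0.18 (adjusted p = 0.0121; adjusted p = 0.653 with an estimated correlation). Its adjusted p was 0.108 without c-kit+ control replicate 2, 0.127 without CD44+ control replicate 1, 0.229 among the brighter genes and 0.0548 with array weights. Over the alternatives the medians ran from 0.09 to 0.51 for the interferon list, from 0.09 to 0.28 for the macrophage list and from -0.35 to -0.14 for the neutrophil list. Those of the niche and bone factor list ran from -0.6 to -0.12 and those of the mesenchymal list from -2.64 to -0.66. Without c-kit+ control replicate 1 (238 genes) Fcgr1, C1qb, Mrc1 and Csf3r lost their calls. C1qb and Csf3r did without c-kit+ control replicate 2 (386 genes), and Fcgr1 and Mrc1 without replicate 3 (456 genes). Fcgr1, Mrc1 and Csf3r did without CD44+ control replicate 1 (339 genes) or 2 (414 genes). Without CD44+ control replicate 3 (221 genes) all 4 did, and 10 lists passed, the number that the replicate block gave as well. With the mean of a gene's probe sets (436 genes) Fcgr1 and C1qb lost their calls. After quantile normalization over all arrays (439 genes) Fcgr1, Mrc1 and Csf3r did, and after that within each cell type (494 genes) Mrc1 and Csf3r.

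The other 18 lists did not pass camera (adjusted p from 0.0533 to 0.981, medians from -0.15 to 0.17), with 3 members higher in c-kit+ and 14 higher in CD44+ cells. In the stem and progenitor list (adjusted p = 0.0533) the transcription factor gene Lmo2 was higher in c-kit+ cells (0.74, adjusted p = 0.0165), and 20 of 22 did not pass. The homeobox gene Hoxa9 of that list was higher in CD44+ cells (-2.21, adjusted p = 0.00396). In the dendritic cell and MHC class II list (adjusted p = 0.0533) 4 of 17 genes were higher in CD44+ cells, H2-Aa (-1.47), Cd74 (-1.41), H2-Eb1 (-1.29) and H2-Ab1 (-1.1), all of which act in antigen presentation. The remaining calls were Cd22 (0.88) and Fabp4 toward c-kit+ cells, and Ebf1 (-1.46), Scd1 (-1.71), Hspa1b (-1.51), Klf4 (-0.97), Klf2 (-0.75), Krt19, Dcstamp (-1.04), Eda2r (-1.14) and, again, Cxcl12 toward CD44+ cells. Without c-kit+ control replicate 1 (238 genes) Lmo2, Fabp4, H2-Ab1, Cd22, Ebf1, Krt19, Dcstamp and Eda2r lost their calls. Lmo2, Fabp4, Ebf1, Scd1, Klf2, Krt19 and Eda2r did without CD44+ control replicate 3 (221 genes). H2-Ab1, Ebf1, Klf4, Klf2 and Eda2r did without c-kit+ control replicate 2 (386 genes), and H2-Ab1, Klf2, Krt19 and Eda2r without replicate 3 (456 genes). H2-Aa, H2-Ab1, Cd22, Ebf1, Klf4, Klf2, Krt19, Dcstamp and Eda2r did without CD44+ control replicate 1 (339 genes), and H2-Aa, H2-Ab1, Fabp4 and Klf2 without replicate 2 (414 genes). The median, the mean and the direction of the test differed in sign for the erythroid, megakaryocyte, cell cycle, and immediate early and dissociation stress lists.

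**Figure D3:**
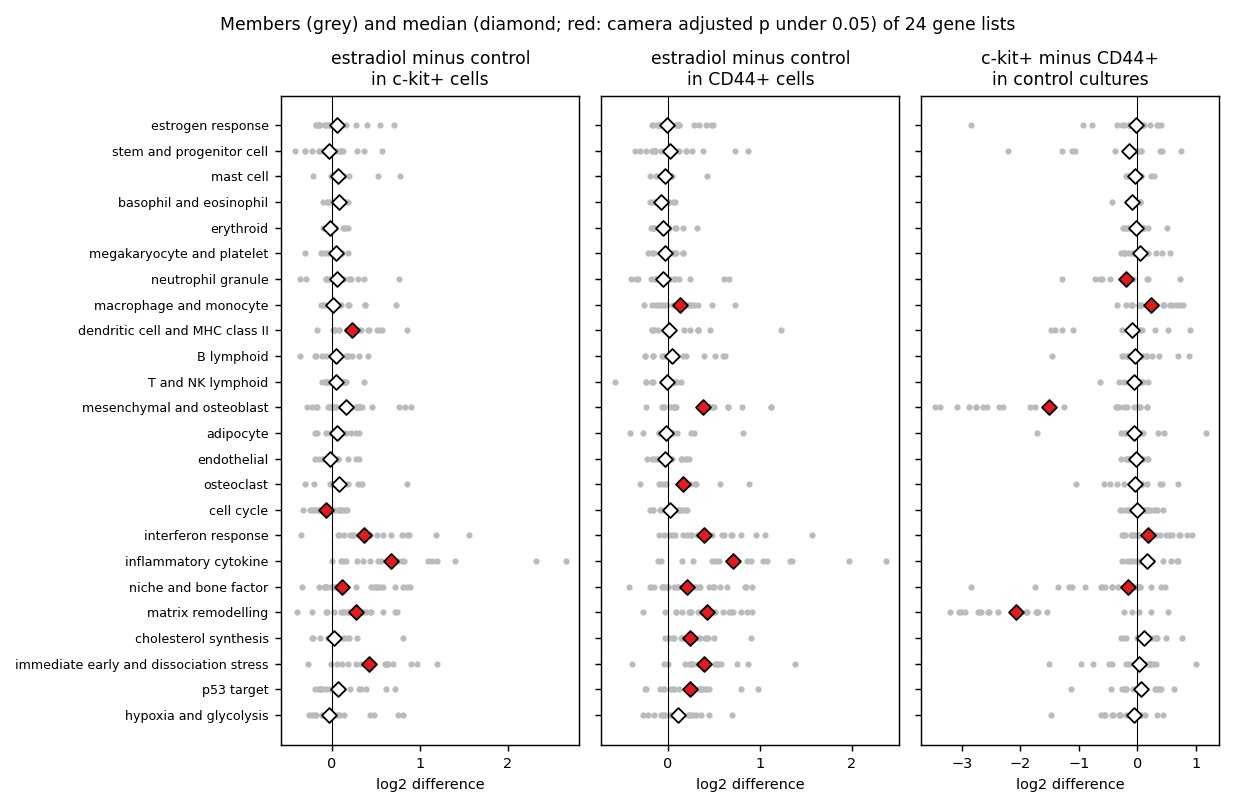
Log2 differences of the measured members (grey points) and their median (diamond, red where the camera adjusted p was under 0.05) for the 24 lists in the c-kit+ estradiol, CD44+ estradiol and control fraction comparisons. The inflammatory cytokine list has the highest median in both estradiol panels (0.68 and 0.71), and the matrix remodelling list the lowest in the fraction panel (-2.08).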

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

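The tests of the macrophage share, of RNA quality, of a microbial ligand, of the Kit probe sets, of shared cells and of the replicate numbers, with RNA quality among the numbers, were chosen only after the results were seen. For RNA quality several tests were tried in turn (the list median with a covariate, pairs of arrays split by the Gapdh measure, and the list score with a covariate, first against 0.5 of the effect and then against 0).

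Signals outside the named genes were looked for in the 10092 probe sets that name no gene or several (unnamed here). With estradiol 6 of them changed in c-kit+ cells (4 higher, 2 lower, largest rise 1.6 on the log2 scale) and 15 in CD44+ cells (14 higher, 1 lower, largest rise 1.77), 3 of them in both. Of the 64 control probe sets 0 changed in limma in either cell type (1 and 7 had an unadjusted p under 0.05). Single outlying arrays were not tested for in groups of 3 (c-kit+ control replicate 3 stood apart, with 555 genes over 2-fold from the rest of its group), and no gene passed the test of a difference between the effects in both cell types.

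The inflammatory cytokine list was higher in the estradiol arrays of both cell types. A larger share of macrophages would raise macrophage genes of middle level by about as much, but over the 9 of 22 with means between 5 and 12 the median of the inflammatory list lay 0.62 higher in c-kit+ cells (0.68, quartiles 0.34 to 1.11, against 0.05, quartiles -0.01 to 0.11) and 0.72 higher in CD44+ cells (0.71, quartiles 0.51 to 1.04, against -0.01, quartiles -0.1 to 0.23), and over all 22 by 0.66 and 0.58, which argues against it as the whole cause. RNA quality as the whole cause is argued against too, since the Gapdh measure hardly moved with estradiol (-0.07 and 0.07). So balanced a covariate could change the effect little. With it the list score stayed higher by 0.61 in c-kit+ cells (95% interval 0.29 to 0.94, effect 0.62 without it). In CD44+ cells it stayed higher by 0.73 (0.4 to 1.05, 0.72 without it). That the list was higher in all 9 pairs of an estradiol and a control array restates the shift. In CD44+ cells the median was 0.77 in 5 pairs with the higher measure in the estradiol array and 0.73 in 4 others. In c-kit+ cells it was 0.36 in 3 such pairs, all with 1 estradiol array, and 0.63 in 6 others. The lowest c-kit+ pair (0.35) was no larger than the largest difference within a group there (0.35). In c-kit+ cells the interval also reaches below 0.5 of the effect. The SE was 0.14 with and without the covariate, so this reach comes from the spread between arrays. It does not decide whether RNA quality is a part of the effect, which stays open. A microbial ligand in the treated cultures might raise the same genes: 5 list members rose in both cell types, but estradiol predicts this too, and since a ligand would have come with the treatment, the explanations cannot be told apart. The effect of estradiol itself, which the design names, stays open beside it.

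Kit, near background on all arrays, did not differ past the threshold between the fractions (log2 difference -0.04, SE 0.12), although 1 fraction is named for its protein. If the Kit probe sets had failed in a fraction of progenitors, other stem and progenitor genes could be higher in c-kit+ cells; 1 of 22 was (Lmo2) and 1 was lower (Hoxa9) in control cultures, and in estradiol cultures 0 were higher and 4 lower (list adjusted p = 0.0486; adjusted p = 0.177 with an estimated correlation), which goes against it, but with members that go both ways, few calls and several near background (Gfi1 3.36, Prom1 3.52) this cannot be told apart from a fraction with little Kit mRNA. If the fractions shared most of their cells, which may be macrophages, the macrophage list would differ little: its median difference was 0.23 (quartiles 0.02 to 0.45, members from -0.35 to 0.78, 3 of 22 called). Members near the top of the scale, such as Csf1r (14.05 in c-kit+ and 13.99 in CD44+ control arrays), may differ little in any case. A small median thus does not decide the question of shared cells, and members both near 0 and called keep it open. The matrix remodelling list, with its median of -2.08, shows that the fractions were not alike throughout. The design gives no group that would test a biological explanation, and none was tested.

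Genes followed the replicate number across the 4 groups. In limma 135 genes differed between the numbers, Mid1 first (means of 9.05, 7.83 and 5.69 for replicates 1, 2 and 3, adjusted p = 1.06e-05), while among 100 relabelings of the numbers within groups, the real one included, the highest other count was 16 and the median 0. This is consistent with replicate numbers that mark shared animals, cultures or processing, and which of these was not tested. The Gapdh measure also followed the number (means of 4.99, 4.27 and 3.79, exact permutation test, p = 0.0139, adjusted p = 0.0278). With it as a covariate in limma 6 genes were left (Mid1 with adjusted p = 0.0102). Of 100 relabelings, the real one included, 3 gave as many, and the highest other count was 17. A covariate that follows the number can lower this count in any case. With the measure in place of the number, 0 genes followed it in limma after adjustment, and 2370 had an unadjusted p under 0.05. So fewer genes passed for the measure than for the number. For most of the 135 genes RNA quality and the number still cannot be told apart. No biological explanation was tested, since the design gives no group for it.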

How the results depend on the processing

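The RNA-quality covariate, the block in estradiol cultures and, for CD44+ cells, the fit without c-kit+ control replicate 3 were chosen only after the data were seen. Among named genes no call changed direction under any alternative; calls were lost in 33 cases and gained in 22 for c-kit+ cells, 43 and 96 for CD44+ cells, and 131 and 47 for the cell types, against 1689, 1771 and 1737 cases with the call as before. For named genes the difference of effects gave 2331 cases, all without a call. Lists that passed lost their call in 21, 39 and 12 cases, kept it in 96, 141 and 89, and turned in 2: the cell cycle list in c-kit+ cells, with medians from -0.098 to 0.014 over the left-out arrays, the positive ones being 0.014 (without control replicate 1) and 0.0042 (without estradiol replicate 2).

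Counts of genes for estradiol in c-kit+ cells, estradiol in CD44+ cells and the cell types, 33, 53 and 418, became 62, 101 and 693 with a replicate block and 55, 1405 and 1058 with array weights. With the 6 arrays of the comparison alone they were 2, 58 and 196. Every probe set tested gave 87 (CD44+) and the RNA-quality covariate 254 (cell types). Estradiol in place of control cultures together with a block gave 662 (cell types). The cause was not tested. With that covariate the median of the inflammatory list was 0.68 in c-kit+ and 0.72 in CD44+ cells, against 0.68 and 0.71 without it. By construction, a change of at least 2-fold lowered the counts to 17, 29 and 244, while with an unadjusted p and at least 1.5-fold, 2 choices at once, they were 160, 248 and 762, and 32 in place of 0 for the difference of effects. Leaving out 1 array gave 10 to 45, 22 to 97 and 221 to 456 genes, and 0 for the difference of effects.

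Counts of lists, 7, 10 and 6, became 2, 1 and 0 with an estimated correlation, which widens the test, and 2, 1 and 7 with fry. They were 6 (CD44+) among the brighter genes and 10 (cell types) with a replicate block. For the difference of effects, 0 lists became 1 with the block, 2 with array weights and 1 with the covariate. Apart from the estimated correlation, the cause was not tested. Leaving out 1 array gave 5 to 8, 7 to 10 and 5 to 10 lists, and 0 to 4 for the difference of effects. The other alternatives stayed within 1.5 times. Background limits dim genes: 9 Y-linked probe sets, in female mice, had means from 2.91 to 3.63.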

Other observations

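The test of the replicate numbers, that of RNA quality by number, the count of genes apart from their group and the counts over other splits of the samples were chosen only after the results they measure were seen; the comparison of the fractions in estradiol cultures was planned, its fit with a block was not.

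In estradiol cultures the fractions differed in 8 lists. These arrays met the pairing criterion, but the labels do not say what the replicate numbers mark. The Gapdh measure followed the number too, so a block may also take up RNA quality. With the number as a block, fitted after the data were seen, the same 8 lists passed (the stem and progenitor list with adjusted p = 0.0147, the neutrophil granule list with 0.0398), and 662 genes differed in place of 483. In that fit the matrix and the mesenchymal list passed with an estimated correlation (adjusted p = 0.0234 for both). Of the 23 matrix remodelling genes 18 were higher in CD44+ cells, and the median difference was -2.4 on the log2 scale (c-kit+ minus CD44+, 3 arrays against 3, adjusted p = 8.98e-39; adjusted p = 0.0333 with an estimated correlation), the list that also passed with an estimated correlation. Of the 24 mesenchymal and osteoblast genes 14 were higher in CD44+ cells (median -1.73, adjusted p = 5.67e-25; adjusted p = 0.0694 with an estimated correlation). Of the 22 stem and progenitor genes 4 were higher in CD44+ cells, the homeobox gene Hoxa9 (-2.98, adjusted p = 0.000479), Cd34 (-1.43, adjusted p = 0.0318), the growth factor gene Angpt1 (-1.32, adjusted p = 0.0327) and Sox4 (-1.75, adjusted p = 0.0375), and 18 did not pass; the list median was -0.033 (adjusted p = 0.0486; adjusted p = 0.177 with an estimated correlation). In the niche and bone factor list 6 of 25 genes were higher in CD44+ cells (median -0.08, adjusted p = 0.000196; adjusted p = 0.177 with an estimated correlation), among them Tgfb2 (-1.69, adjusted p = 0.000478) and Tnfrsf11b, the gene of the osteoclast inhibitor osteoprotegerin (-1.64, adjusted p = 0.0125). None of the 21 hypoxia and glycolysis genes passed (median -0.27, adjusted p = 0.000196; adjusted p = 0.177 with an estimated correlation). The macrophage list, with 2 members higher in c-kit+ cells (C1qb and Mrc1), had a median of 0.09 (adjusted p = 0.00587; adjusted p = 0.34 with an estimated correlation), the interferon list, with 1 (Ifi204), 0.29 (adjusted p = 0.00587; adjusted p = 0.646 with an estimated correlation), and the neutrophil granule list, with none, -0.09 (adjusted p = 0.0486; adjusted p = 0.358 with an estimated correlation). These genes were named after their values were seen.

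Among the 135 genes that differed between the replicate numbers across all 4 groups were genes of several kinds. The serum amyloid gene Saa3 had means of 11.17, 12.83 and 12.73 on the log2 scale in the 4 arrays of replicates 1, 2 and 3 (adjusted p = 0.00491), the chemokine gene Ccl5 10.06, 11.97 and 11.75 (adjusted p = 0.00246), the complement factor gene Cfb 5.65, 7.32 and 7.37 (adjusted p = 0.00281), and Lcn2, which encodes the iron-sequestering protein lipocalin 2, 4.74, 6.69 and 6.08 (adjusted p = 0.000995). Erdr1 had 11.04, 10.79 and 8.63 (adjusted p = 0.000986), the collagen gene Col4a1 9.23, 8.29 and 8.7 (adjusted p = 0.00915), and the cell cycle gene Ccnb2 10.24, 9.76 and 9.58 (adjusted p = 0.0377). Saa3 and Ccl5 belong to the inflammatory cytokine list, so members of that list also differed between the replicate numbers. Between replicates 1 and 2 both moved by more than the median change of the whole list with estradiol (0.68 and 0.71), which is not their own change. Every group holds each replicate number, so a difference between numbers is balanced between estradiol and control arrays. No theme among the 135 genes was tested. The 3' to 5' difference of Gapdh was highest in replicate 1 in all 4 groups (means of 4.99, 4.27 and 3.79), and that of Actb had means of 3.12, 2.55 and 2.03 (exact permutation test over 216 relabelings, p = 0.0139 and 0.0787, adjusted p = 0.0278 and 0.0787). These genes, too, were named after their values were seen.

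The array of c-kit+ control replicate 3 stood apart from its group: 555 genes (3.05%) lay over 2-fold from the other 2 arrays of the group, against 10 to 114 genes on each of the other arrays.

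The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. For c-kit+ cells the real split gave 33 genes and the highest other 1 (1 split gave as many, the real one), and 7 lists against 5 (1 split). For CD44+ cells it gave 53 genes against 1 (1 split), and 10 lists against 10 (2 splits); among the 4 splits that part the 3 pairs of replicate numbers the highest other counts were 0 genes and 10 lists. For the cell types it gave 418 genes against 0 (1 split), and 6 lists against 8 (3 splits). For the difference of effects, where the real counts were 0 genes and 0 lists, all of 100 drawn splits had to give as many (100 for genes and 100 for lists), which says nothing about chance; the highest other counts were 173 genes and 10 lists. The split with 173 genes swaps all treatment labels of the CD44+ arrays, so that both effects add up, which is the structure of shared effects.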
